A study of Mus musculus with 12 samples.

How the data were processed

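RNA of sorted epithelial cells from mouse skin wounds was sequenced in 12 libraries, 3 for each combination of genotype (wild type or RORγt-deficient) and integrin alpha5 status (A5-positive or A5-negative). The libraries were made with SMART-Seq v4 for low input and with ThruPLEX. The submitters' processing notes name bcl2fastq, Trimmomatic 0.36, STAR and featureCounts and the genome build mm10, which is GRCm38. The annotation release, the strand setting of the counting and the treatment of reads that match several places are not given in the sources used here. The deposited table holds raw read counts per gene symbol, as whole numbers with no normalization by the authors.

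The table had 55341 rows. A spreadsheet had turned 26 gene symbols into dates, and these rows, with 0.110% to 0.128% of the counts of a library, were left out. All 55315 other symbols matched GENCODE M21, from which positions and gene types were taken. Total counts per library ran from 29293687 to 74563616, and 14946 to 17538 genes had at least 10 counts. Limits set by depth cover counting error only, since reads without molecular identifiers are not independent molecules. Within each group no pair of libraries was alike to within counting error, and pairs across groups were not compared.

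Counts were analysed with edgeR 4.0.16 in R 4.3.3, using TMM factors of 0.919 to 1.08, filterByExpr by group (16677 genes tested), 1 model of the 4 groups over all 12 libraries and the quasi-likelihood F test. P-values were adjusted by Benjamini and Hochberg (BH) within each of 5 comparisons, with a threshold of 0.05. The comparisons were the A5 effect in each genotype (A5-positive against A5-negative), the genotype effect in each fraction (RORγt-deficient against wild type) and their interaction. Changes are log2 fold changes with a standard error (SE) of the change divided by the root of F. Levels are CPM values scaled by TMM, with the standard deviation (SD) over 3 libraries, unless they are named as CPM of the total counts. The p-values measure the spread between pools of 2 or 3 mice, not between single mice.

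There were 31 gene lists, and 29 had at least 3 tested members. They covered wound-front keratinocytes, actin and adhesion, hypoxia, glycolysis, oxidative phosphorylation, the IL-17 response of keratinocytes, IL-17 receptor and signalling, the mTORC1, AKT and ERK pathway, and cholesterol synthesis. Further lists held basal and differentiating keratinocyte genes, hair follicle epithelium, proliferation, the type I interferon response, extracellular matrix and basement membrane, dissociation stress, the unfolded protein and integrated stress response, and mitochondrially encoded genes. Marker lists covered T cells, macrophages and monocytes, neutrophils, Langerhans and dendritic cells, mast cells, fibroblasts, endothelial cells, melanocytes, sebocytes, muscle, adipocytes, erythroid cells and Schwann cells. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01 on log2 CPM with a prior count of 2, and BH ran over the lists of a comparison. Every list passing this test lost that call when the correlation was estimated per list, and that p is given beside each.

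The groups, the tests, the gene lists, the rule for naming genes and the first set of alternatives were chosen before the data were examined. The rule took the sort and exclusion markers, Hif1a, Slc2a1 and Il17ra in every comparison, and some items that it took are not reported here. It added the genes with the largest rise and fall among those past the threshold with a mean log2 CPM of at least 3 and groups that do not overlap. Where fewer than 3 qualified it took those with the smallest p, and from each list the members with the smallest p. Genes outside this rule are named as chosen after their values were seen.

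The labels number the libraries of each group from 1 to 3. Residuals after group means, over 9071 genes, correlated above 0.1 for all 18 pairs of libraries with the same number (0.153 to 0.722, median 0.452). The 36 pairs with different numbers had a median of -0.24 and a maximum of 0.315. The numbers therefore pair the libraries, and a fit with the number as a block is given beside a result wherever it changes a call or moves a count by more than 1.5 times. The alternatives in the first set were RLE size factors, DESeq2 1.42.0, no filter, a stricter filter (CPM of 5 in 3 libraries), the block, a block by genotype and number, voom with quality weights, the 6 compared libraries alone, and leaving out each library. For the lists they were an estimated correlation, fry, the block, RLE factors and a prior count of 0.5. After seeing the data, the following were added: leaving out all libraries of a number, the mean of the fibroblast markers as a covariate, these and other tools with the block, and the naming rule applied to the fit with the block.

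The fits were tested on counts simulated from the fitted model with the block and its spread, with 200 changed genes above a minimum level. Without the block they recovered 48% to 59% of 2-fold changes in the 4 comparisons of groups and 15% in the interaction, and 96% to 98% and 83% of 4-fold changes, with no false call. With the block they recovered 87% to 90%, and 51% in the interaction, of 2-fold changes, and 3.55% to 6.86% of the calls were false. Since the counts were drawn from the model with the block, this favours that fit. It does not show how stable the calls on the real libraries are. The biological coefficient of variation was 0.302, and 0.224 with the block. Near-identical sequences were sought with BLAST 2.17.0, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, tests and plots.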

Results

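Keratinocytes were sorted from mouse skin 3 days after wounding, from a ring of 0.25 mm at the wound edge, with 2 or 3 mice pooled for each group and sequencing run. Live cells positive for Epcam and for integrin alpha6 were taken, and cells with CD45, CD31 or CD117 were excluded. Integrin alpha5, the product of Itga5, split them into A5-positive cells, which the study assigned to the migrating tongue of the wound, and A5-negative cells of the adjoining wound edge. The mice were wild type or deficient in RORγt, the transcription factor of IL-17-producing lymphocytes, through a GFP knock-in. The series is about how IL-17 shapes the adaptation of injured epithelium to low oxygen.

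RNA sequencing gave 3 libraries in each of 4 groups. The wild-type A5-negative libraries 1 to 3 had total counts of 51694159, 35292984 and 34821197, and the wild-type A5-positive libraries had 57391411, 33214238 and 29293687. The RORγt-deficient A5-negative libraries had 74563616, 38057652 and 31656284, and the A5-positive libraries had 52783580, 33682375 and 37746642. Mitochondrially encoded genes took 0.312% to 0.853% of the counts. Below, a change is a log2 fold change ± SE, and a level is a mean in CPM ± SD (n = 3).

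Itga5 (GRCm38 chromosome 15, 103344286 to 103366763) followed the sort, with 46.8 ± 4.92 and 54.2 ± 6.92 in A5-negative against 94.4 ± 8.33 and 122 ± 14.7 CPM in A5-positive cells of wild-type and RORγt-deficient mice. The sort markers Epcam (520 to 798 CPM as group means) and Itga6 (649 to 852 CPM) were high in all groups. Ptprc, which encodes CD45, was lower, with 17.5 ± 19.2 and 17.1 ± 11.8 CPM in A5-negative and 3.72 ± 0.975 and 5.24 ± 1.68 CPM in A5-positive cells. Kit, which encodes CD117, had group means of 5.35 to 7.89 CPM, and Pecam1, which encodes CD31, of 1.38 to 6.21 CPM. In a principal component analysis the leading component took 53.6% of the variance and the next 18.3%. Within each genotype every A5-positive library scored higher on the leading component than every A5-negative library.

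The A5 effect in wild-type mice asked how the migrating tongue differs from the wound edge. As lists, wound-front keratinocyte, cell division, glycolysis and matrix genes and fibroblast markers were higher in A5-positive cells, and differentiation and dissociation-stress genes were lower. The call for differentiation genes ended without some single library, as given below. Krt6a, a keratin of wounded epidermis (chromosome 15, 101689910 to 101694307), rose by 1.95 ± 0.32, from 503 ± 50.9 to 1938 ± 566 CPM (edgeR quasi-likelihood, adjusted p = 0.00704). Tpx2, a spindle assembly factor (chromosome 2, 152847964 to 152895321), rose by 1.55 ± 0.19, from 18.8 ± 1.41 to 55.2 ± 7.31 CPM (adjusted p = 0.00124). Col3a1, a collagen of fibroblasts (chromosome 1, 45311538 to 45349706), rose by 5.31 ± 0.82, from 64.8 ± 38.1 to 2563 ± 989 CPM (adjusted p = 0.0052).

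In all, 575 of 16677 genes changed, 520 up and 55 down, and 2394 (1461 up and 933 down) with the replicate block. The levels did not overlap between the groups for 4171 genes (25%), against 10% by chance. They did not overlap for 21 of the 21 named genes that passed, and 27 of the 30 that passed with the block (not Epcam, Il17ra and Cdh1). Part of the named genes were picked for levels that do not overlap, so this is no added support. The count was 378, 255 and 156 without wild-type A5-negative library 1, 2 or 3, and 282 and 365 without wild-type A5-positive library 1 or 2. With the block these counts were 861, 1436 and 579, and 843 and 776.

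Of 40 tested proliferation genes, 29 rose (36 adjusted over the list alone), with a median of 1.22 (camera adjusted p = 7.37e-24, and adjusted p = 0.514 with an estimated correlation). Among them were Kif20a, a kinesin of cytokinesis (1.77 ± 0.26, adjusted p = 0.00363), the mitotic kinase gene Aurka (1.21 ± 0.19, adjusted p = 0.00517) and Rrm2, a subunit of ribonucleotide reductase (1.0 ± 0.16, adjusted p = 0.0052). Of 36 wound-front keratinocyte genes, 9 rose, and with the block 16 rose and 3 fell. Adjusted over the list alone, 12 rose and 1 fell. The median was 0.45 (camera adjusted p = 0.00146, and adjusted p = 0.514 with an estimated correlation). Itga5 rose by 1.01 ± 0.14 (adjusted p = 0.00293) and Krt16, another keratin of wounded epidermis, by 1.10 ± 0.23 (adjusted p = 0.0229). The Krt16 call ended without wild-type A5-negative library 1 (adjusted p = 0.0766), 2 (0.0641) or 3 (0.0891) and without A5-positive library 1 (0.101) or 3 (0.0504). With the block it ended without A5-negative library 1 (0.058) or 3 (0.0573).

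Of 22 glycolysis genes, 8 rose (13 adjusted over the list alone) and 12 with the block, with a median of 0.60 (camera adjusted p = 5.82e-05, and adjusted p = 0.613 with an estimated correlation). Eno1, which encodes enolase, rose by 0.89 ± 0.18, from 549 ± 17.6 to 1018 ± 258 CPM (adjusted p = 0.0214). Pkm, the pyruvate kinase gene (chromosome 9, 59656368 to 59679375), rose by 0.94 ± 0.21, from 1332 ± 190 to 2563 ± 746 CPM (adjusted p = 0.0279). Slc16a3, a lactate transporter, rose by 1.76 ± 0.37 (adjusted p = 0.024). The Eno1 call ended without wild-type A5-negative library 1 (adjusted p = 0.054), 2 (0.0744) or 3 (0.0986) or A5-positive library 1 (0.0611). For Pkm it ended without A5-negative library 1 (0.0821) or 3 (0.142) or A5-positive library 1 (0.106) or 2 (0.0691), and for Slc16a3 without A5-negative library 2 (0.0835) or 3 (0.12) or A5-positive library 1 (0.0853). With the block none of these 3 calls ended (highest adjusted p = 0.0352, 0.0322 and 0.0143).

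The hypoxia-response list shares Slc2a1, Hk2, Pfkfb3, Pfkfb4, Aldoa, Tpi1, Pgk1, Eno1, Ldha, Slc16a3 and Pdk1 with the glycolysis list. Results of these lists are therefore not separate. Of 44 hypoxia-response genes, 6 rose, and with the block 13 rose and 3 fell, while adjusted over the list alone 14 rose and 1 fell. The median was 0.28 (camera adjusted p = 0.0327, 0.0923 with the block, and adjusted p = 0.675 with an estimated correlation), and the call ended without wild-type A5-negative library 1 (adjusted p = 0.184). The median was 0.16 without A5-positive library 1. Slc2a1, the glucose transporter GLUT1 (chromosome 4, 119108711 to 119137983), had 529 ± 8.29 CPM in A5-negative and 965 ± 401 CPM in A5-positive cells, where the libraries had 1427, 720 and 748 CPM. Its change of 0.87 ± 0.24 had an adjusted p of 0.0707, and it rose with the block by 0.81 ± 0.18 (adjusted p = 0.0181). That call ended without A5-negative library 1 (0.0845) or 3 (0.0693), and the value was 0.51 without A5-positive library 1. Hif1a, the oxygen-regulated transcription factor, had a change of 0.40 ± 0.15 (adjusted p = 0.173).

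All 40 tested genes of oxidative phosphorylation had a change above 0, with a median of 0.43 (camera adjusted p = 7.46e-06, and adjusted p = 0.689 with an estimated correlation), and 0.28 without wild-type A5-negative library 2 and 0.22 without A5-positive library 1. Single members passed only with the block, where 7 rose (28 adjusted over the list alone). Sdhd, a subunit of succinate dehydrogenase, rose by 0.78 ± 0.17 with the block (adjusted p = 0.0144), and this ended without A5-negative library 1 (0.0546) or 3 (0.0776) or A5-positive library 1 (0.0703) or 2 (0.0633). The basal keratins Krt14 and Krt5 rose with the block by 0.84 ± 0.13 (adjusted p = 0.00308) and 0.77 ± 0.13 (adjusted p = 0.00402). The list of 20 basal keratinocyte genes, with a median of 0.23, passed with the block (camera adjusted p = 0.0329, against 0.164 without it, and adjusted p = 0.523 with the block and an estimated correlation). Cholesterol synthesis (25 genes, median 0.16, 0.0329 against 0.0837, and adjusted p = 0.616 with an estimated correlation) and the type I interferon response (26 genes, median 0.24, 0.0112 against 0.0643, and adjusted p = 0.616 with an estimated correlation) passed with the block as well.

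Fibroblast markers were the list with the largest median change. Of 17, 15 rose (15 adjusted over the list alone), with a median of 4.79 (camera adjusted p = 6.89e-22, and adjusted p = 0.158 with an estimated correlation). Their summed level per library was 229 to 375 CPM of the total counts in A5-negative and 4551, 6726 and 9047 CPM in A5-positive cells. Lum, which encodes the proteoglycan lumican, rose by 4.95 ± 0.53 (adjusted p = 0.000404) and Pdgfra, a growth factor receptor of fibroblasts, by 4.79 ± 0.32 (adjusted p = 3.13e-05). Eln, the elastin gene, rose by 6.17 ± 0.52 (adjusted p = 0.00013). Of 25 genes of matrix and basement membrane, 9 rose (12 adjusted over the list alone) and 14 with the block, with a median of 0.78 (camera adjusted p = 1.92e-06, and adjusted p = 0.514 with an estimated correlation). They included Sparc, a matrix protein of many mesenchymal cells (3.19 ± 0.45, adjusted p = 0.00319), and Col4a1, a collagen of basement membranes (1.07 ± 0.16, adjusted p = 0.00477). Cd34, listed as a hair follicle gene and also known from fibroblasts and vessels, rose by 2.82 ± 0.47 (adjusted p = 0.00749).

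Lower in A5-positive cells were Skint6, an epidermal member of the butyrophilin-like family (-1.57 ± 0.35, adjusted p = 0.0302), the kinase inhibitor gene Pkib (-1.32 ± 0.24, adjusted p = 0.0124) and Calm5, a calmodulin-like gene of differentiating keratinocytes (-1.04 ± 0.19, adjusted p = 0.0123). The Skint6 call ended without wild-type A5-negative library 2 (adjusted p = 0.0827) or 3 (0.136) or A5-positive library 1 (0.0518) or 2 (0.0583). Pkib lost it without A5-negative library 3 (0.0715), and Calm5 without A5-negative library 3 (0.0771) or A5-positive library 2 (0.0538). With the block none of these 3 calls ended (highest adjusted p = 0.0264, 0.03 and 0.0257). Of 27 genes of differentiating keratinocytes, 1 fell (1 adjusted over the list alone), and with the block 9 fell and 1 rose. The median of -0.40 (camera adjusted p = 0.0124, and adjusted p = 0.689 with an estimated correlation) went to -0.14 without A5-negative library 3 (0.189), to -0.09 without A5-positive library 1 (0.135) and to -0.21 without A5-positive library 2 (0.121), which ended the call, and to -0.83 without A5-positive library 3. All 26 dissociation-stress genes, immediate early genes that rise when tissue is digested, had a change below 0, with a median of -0.39 (camera adjusted p = 3.76e-07, and adjusted p = 0.613 with an estimated correlation). With the block 10 of them fell (14 adjusted over the list alone). Epcam fell with the block (-0.56 ± 0.14, adjusted p = 0.0262), and this ended without A5-negative library 1 (0.106) or 3 (0.0922) or A5-positive library 1 (0.128) or 2 (0.0991). Il17ra, a subunit of the IL-17 receptor, did so as well (-0.52 ± 0.14, adjusted p = 0.0381), until A5-negative library 1 (0.130) or 3 (0.177) or A5-positive library 1 (0.189) or 2 (0.122) was left out.

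Markers of macrophages and monocytes (19 genes, median -2.25, camera adjusted p = 5.82e-05, and adjusted p = 0.689 with an estimated correlation) were lower in A5-positive cells. None passed over all genes, and 19 fell adjusted over the list alone. Their summed level was 1754, 118 and 379 CPM of the total counts in the A5-negative and 132, 130 and 215 CPM in the A5-positive libraries. Without A5-negative library 1 the median was -0.67 and the call ended (adjusted p = 0.12). Langerhans and dendritic cell markers (12 genes) had a median of -1.64 (camera adjusted p = 0.015, and adjusted p = 0.689 with an estimated correlation). Their call ended without A5-negative library 1 (median -0.28, adjusted p = 0.529) and without A5-positive library 1 (0.0866) or 2 (0.0607). Sebocyte markers (13 genes) had a median of -0.68 (camera adjusted p = 0.0215, and adjusted p = 0.689 with an estimated correlation). This ended without A5-negative library 3 (-0.27, adjusted p = 0.258) and without A5-positive library 1 (-0.35, 0.134) or 2 (-0.34, 0.241), and the median was -1.07 without A5-negative library 2 and -1.95 without A5-positive library 3.

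**Figure D1:**
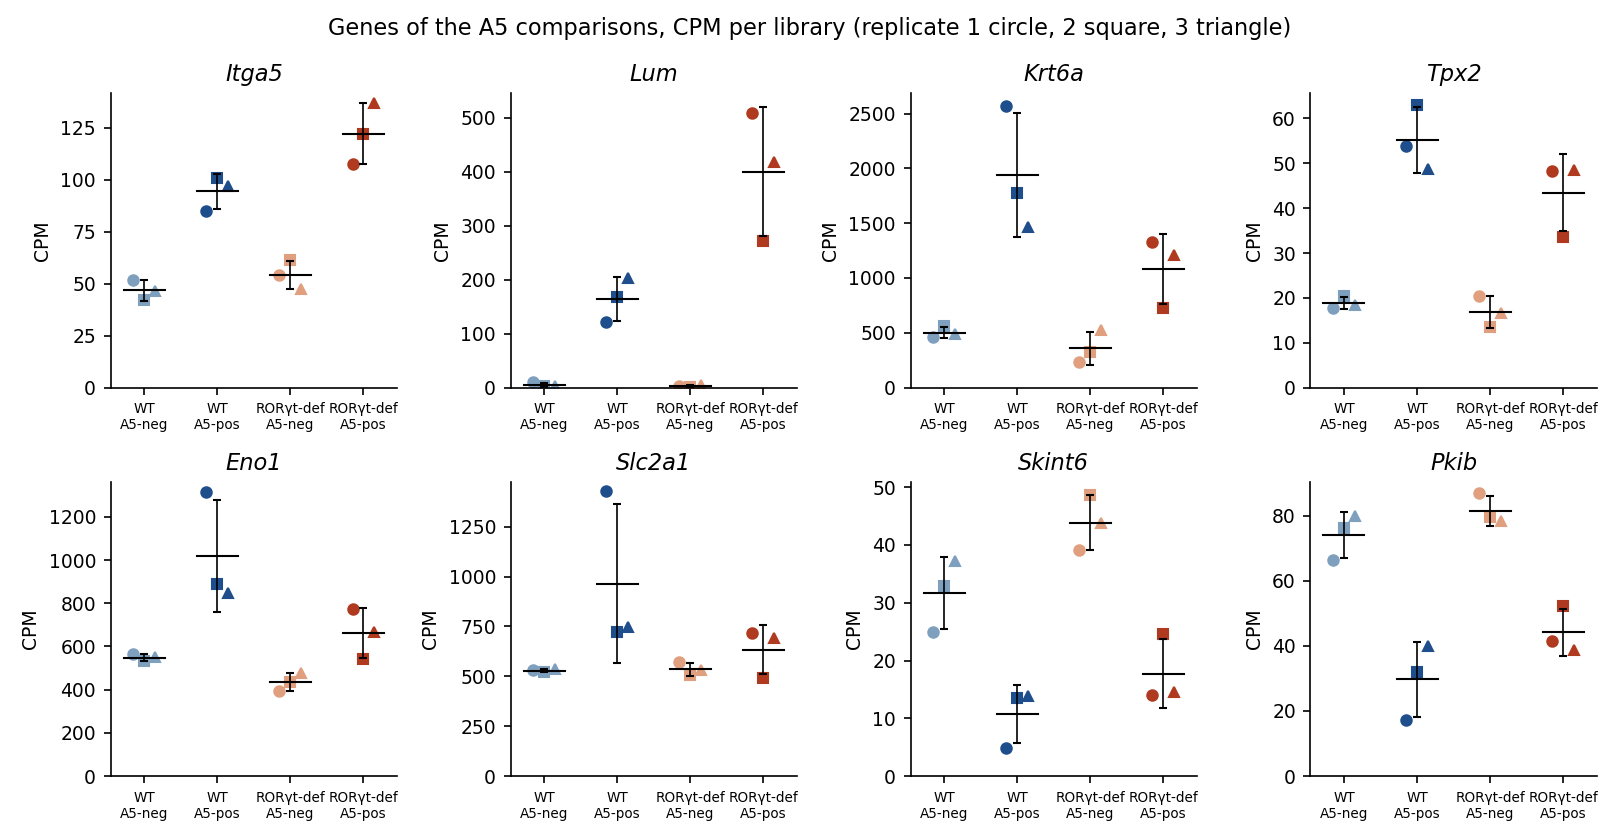
Levels of 8 genes in each of the 12 libraries, in TMM-scaled CPM, with points for libraries and the mean ± SD of each group (n = 3). Lum was at 5.23 ± 3.90 and 2.93 ± 1.45 CPM in the A5-negative groups against 165 ± 40.4 and 400 ± 119 CPM in the A5-positive groups of wild-type and RORγt-deficient mice.

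The A5 effect in RORγt-deficient mice put the same question to mice without RORγt. As lists, division genes, matrix genes and fibroblast markers were again higher in A5-positive cells, and differentiation genes were lower. Krt6a rose by 1.60 ± 0.32, from 359 ± 152 to 1086 ± 319 CPM (adjusted p = 0.0113). Top2a, the topoisomerase of dividing cells, rose by 1.44 ± 0.22, from 57.8 ± 15.4 to 157 ± 41.3 CPM (adjusted p = 0.00203). Lum rose by 7.10 ± 0.58, from 2.93 ± 1.45 to 400 ± 119 CPM (adjusted p = 3.41e-05). The Krt6a call ended without RORγt-deficient A5-negative library 2 (adjusted p = 0.0625) or A5-positive library 1 (0.0549), and with the block it was kept without each of the 6 (highest 0.0408).

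Of the 16677 genes, 921 changed, 760 up and 161 down, and 2937 (1679 up and 1258 down) with the block. Groups did not overlap for 4262 genes (25.6%), against 10% by chance. The same held for 18 of the 18 named genes that passed, and 25 of the 26 that passed with the block (not Cdh1), but part of these were picked for it. The count was 563, 466 and 484 without RORγt-deficient A5-negative library 1, 2 or 3, and 476, 1731 and 475 without A5-positive library 1, 2 or 3. With the block it was 1321 without A5-negative library 1 and 1426 and 1073 without A5-positive library 1 or 3. Of the genes that rose, 404 were shared with the 520 of wild-type mice, where 23.7 would be shared by chance, and of those that fell, 21 were shared with the 55 of wild-type mice, against 0.531. With the block 980 rises were shared with the 1461 of wild-type mice, against 147, and 561 falls with the 933, against 70.4.

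Of 40 proliferation genes, 34 rose (37 adjusted over the list alone), with a median of 1.34 (camera adjusted p = 2.38e-25, and adjusted p = 0.553 with an estimated correlation), among them the kinetochore gene Cenpe (1.48 ± 0.21, adjusted p = 0.00134). Of 36 wound-front genes, 6 rose (9 adjusted over the list alone), and with the block 10 rose and 1 fell. The median was 0.32 (camera adjusted p = 0.00779, and adjusted p = 0.689 with an estimated correlation). The call ended without A5-positive library 2 (0.11, adjusted p = 0.145), and the median was 0.12 without A5-negative library 1 and 0.17 without A5-negative library 3. Itga5 rose by 1.17 ± 0.14 (adjusted p = 0.000468) and Tnc, the tenascin of wound matrix, by 2.35 ± 0.40 (adjusted p = 0.00466). Rhoc, a GTPase of cell migration, rose by 2.05 ± 0.37 (adjusted p = 0.00652), the member of the 31 actin and adhesion genes that passed (1 adjusted over the list alone, and 4 rose and 2 fell with the block). That list had a median of 0.11 (camera adjusted p = 0.253).

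All 40 genes of oxidative phosphorylation were above 0, with a median of 0.57 (camera adjusted p = 1.96e-07, and adjusted p = 0.756 with an estimated correlation), and of 0.29 without A5-positive library 1. With the block 21 rose (38 adjusted over the list alone), and Sdhd rose by 0.86 ± 0.17 (adjusted p = 0.00713). The 8 mitochondrially encoded genes had a median of 0.48 and passed with the block (camera adjusted p = 0.016, against 0.253 without it, and adjusted p = 0.648 with the block and an estimated correlation). Glycolysis genes had a median of 0.31 (camera adjusted p = 0.166), with 6 up and 1 down adjusted over the list alone, and 7 up and 1 down with the block over all genes. Gapdh, a glycolytic dehydrogenase, rose with the block by 0.81 ± 0.18 (adjusted p = 0.012), and this ended without A5-negative library 1 (0.0547) or A5-positive library 1 (0.0607) or 3 (0.0654). Hypoxia-response genes had a median of 0.08 (camera adjusted p = 0.362). Slc2a1, at 535 ± 33.7 and 633 ± 124 CPM, had a change of 0.24 ± 0.24 (adjusted p = 0.57), and Hif1a one of 0.05 ± 0.15 (adjusted p = 0.885). The 22 genes of the unfolded protein and integrated stress response had a median of 0.40 (camera adjusted p = 0.041, 0.0624 with the block, and adjusted p = 0.689 with an estimated correlation), with 1 rising (9 up and 1 down adjusted over the list alone, and 8 up and 2 down with the block). That call ended without A5-negative library 1 (adjusted p = 0.26) or 3 (0.0635) and without A5-positive library 2 (0.22) or 3 (0.0512).

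Of 17 fibroblast markers, 15 rose (17 adjusted over the list alone), with a median of 5.52 (camera adjusted p = 2.02e-25, and adjusted p = 0.0998 with an estimated correlation). Their summed level was 640, 145 and 170 CPM of the total counts in the A5-negative and 16831, 10680 and 17522 CPM in the A5-positive libraries. Dcn, the decorin gene, rose by 7.08 ± 0.62 (adjusted p = 5.25e-05), Col3a1 by 6.31 ± 0.86 (adjusted p = 0.00108) and Serpina3n, a secreted protease inhibitor, by 6.35 ± 0.44 (adjusted p = 1.82e-05). Of 25 matrix genes, 10 rose (10 adjusted over the list alone), with a median of 0.80 (camera adjusted p = 2.38e-06, and adjusted p = 0.689 with an estimated correlation), and of 0.46 without A5-positive library 3. Cd34 rose by 5.04 ± 0.52 (adjusted p = 0.000172), and Saa3, an acute-phase gene of the IL-17 response list, by 6.03 ± 1.13 (adjusted p = 0.00833). Lck, a kinase of T cells, rose by 2.32 ± 0.39, from 0.625 ± 0.0989 to 3.15 ± 1.51 CPM (adjusted p = 0.0045). Of 6 T cell markers 1 rose (2 with the block), with a median of 0.42 (camera adjusted p = 0.253, and 0.0182 by fry). Cd3e, too low to be tested, had 29, 4 and 4 counts in the A5-negative and 4, 0 and 0 in the A5-positive libraries.

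Among the genes that fell, Nfatc2, a calcium-regulated transcription factor, had a change of -1.66 ± 0.38 (adjusted p = 0.0259), Skint6 of -1.31 ± 0.34 (adjusted p = 0.0463) and Notch3, a receptor of differentiating keratinocytes, of -0.93 ± 0.20 (adjusted p = 0.0183). The Skint6 call ended without A5-negative library 1 (adjusted p = 0.0891), 2 (0.131) or 3 (0.112) or A5-positive library 1 (0.184) or 3 (0.182). For Nfatc2 it ended without A5-negative library 2 (0.0632) or 3 (0.0948) or A5-positive library 1 (0.12) or 3 (0.0621), and for Notch3 without A5-negative library 3 (0.078) or A5-positive library 1 (0.0834) or 3 (0.0723). With the block none of the 3 ended (highest adjusted p = 0.0347 for Skint6, 0.00368 for Nfatc2 and 0.0122 for Notch3). Of 27 differentiation genes, 1 fell (4 adjusted over the list alone) and 11 with the block, with a median of -0.50 (camera adjusted p = 0.000975, and adjusted p = 0.756 with an estimated correlation). Dissociation-stress genes had a median of -0.40 with all 26 below 0 (camera adjusted p = 2.22e-05, and adjusted p = 0.689 with an estimated correlation), and 9 fell with the block (17 adjusted over the list alone). Macrophage and monocyte markers had a median of -1.42 (camera adjusted p = 0.0023, and adjusted p = 0.833 with an estimated correlation), which ended without A5-negative library 1 (0.0725) or 3 (0.0635) or A5-positive library 2 (0.0901).

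**Figure D2:**
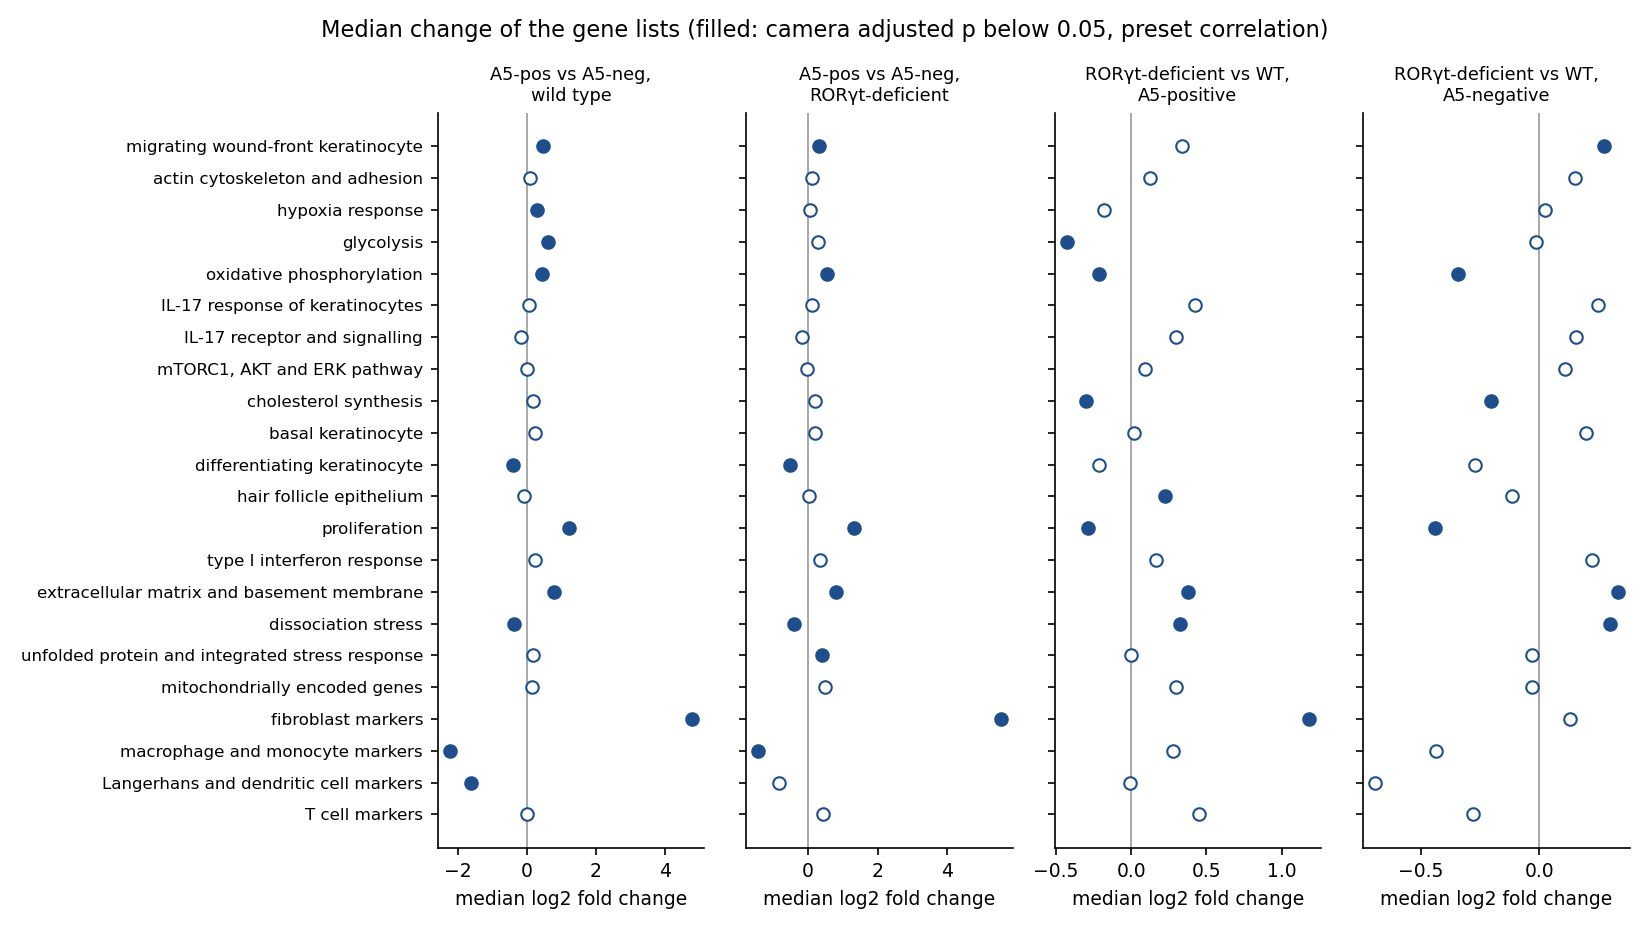
Median log2 fold change of each gene list in the A5 and genotype comparisons, with filled points for lists with a camera adjusted p under 0.05. Fibroblast markers stood at 4.79 and 5.52 in the A5 comparisons of wild-type and RORγt-deficient mice, and proliferation genes at 1.22 and 1.34.

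The genotype effect in A5-positive cells asked what the lack of RORγt changes in the migrating tongue. Glycolysis, cholesterol synthesis, oxidative phosphorylation and proliferation genes were lower as lists in RORγt-deficient cells, and fibroblast, matrix, hair follicle and dissociation-stress genes were higher. The calls for oxidative phosphorylation, proliferation, matrix and hair follicle genes ended without some single library, as given below. None of these lists passed with an estimated correlation. Pkm was at 2563 ± 746 CPM in wild-type and 1579 ± 223 CPM in RORγt-deficient cells (-0.70 ± 0.21, adjusted p = 0.202), and with the block it fell (-0.68 ± 0.16, adjusted p = 0.0447). The pseudogene Gm3608 (chromosome 1, 105455971 to 105458829), named after its values were seen, rose by 4.03 ± 0.15, from 1.57 ± 0.0664 to 25.7 ± 2.39 CPM (adjusted p = 1.03e-07). Its counts cannot be read apart from those of the near-identical Capza1, given below. Thbd, which encodes thrombomodulin (chromosome 2, 148404466 to 148408188), was at 65.5 ± 13.6 and 24.4 ± 4.57 CPM (-1.43 ± 0.27, adjusted p = 0.178), and with the block it fell (-1.41 ± 0.16, adjusted p = 0.00987).

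By edgeR, 1 of 16677 genes, Gm3608, passed, and 670 (377 up and 293 down) with the block. DESeq2 called 380, voom with quality weights 5, and 2497 genes had an unadjusted p under 0.05 (4139 with the block), where 834 are expected by chance. Groups did not overlap for 3011 genes (18.1%), against 10% by chance. The same held for 32 of the 38 named genes that passed with the block (not Il17ra, Pkm, Stfa1, Krt14, Mmp10 and Igfbp3), but part of these were picked for it. The count with the block fell to 6 and 23 without wild-type A5-positive library 1 or 2 and to 86, 14 and 12 without RORγt-deficient A5-positive library 1, 2 or 3. It was 7 (2 up and 5 down) in the 6 compared libraries alone, 114, 1 and 108 without all libraries numbered 1, 2 or 3, and 1 with the mean of the fibroblast markers as a covariate. Of the 38 named genes, 34 lost their call with the block without some library, with adjusted p from 0.0524 to 0.200. That was 34, 30 and 4 genes without wild-type library 1, 2 or 3 and 24, 31 and 33 without RORγt-deficient library 1, 2 or 3, while Gm3608, Gm7665, Klk13 and Ide kept it in all 6. These limits hold for each gene named with the block in the following paragraphs.

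Of 22 glycolysis genes, 3 had a change above 0, and the median was -0.43 (camera adjusted p = 0.000249, and adjusted p = 0.742 with an estimated correlation), or -0.22 without wild-type A5-positive library 1 (0.00434). Over the list alone 6 fell, and with the block 3 fell over all genes and 13 adjusted over the list alone. With the block Pdk1, a kinase that holds back pyruvate oxidation, fell (-0.51 ± 0.11, adjusted p = 0.0377), as did Pfkl, a phosphofructokinase (-0.77 ± 0.16, adjusted p = 0.039). Eno1 was at 1018 ± 258 and 661 ± 115 CPM (-0.62 ± 0.18, adjusted p = 0.202). The summed level of the glycolysis genes was 14969, 10569 and 9257 CPM of the total counts in the wild-type and 9220, 7055 and 8138 CPM in the RORγt-deficient libraries. Fibroblast markers differed between the same libraries, with 4551, 6726 and 9047 against 16831, 10680 and 17522 CPM. Slc2a1 had a change of -0.61 ± 0.24 (adjusted p = 0.279) and Hif1a of -0.22 ± 0.15 (adjusted p = 0.511). Without wild-type A5-positive library 1 these were -0.220 and -0.103. The 44 hypoxia-response genes had a median of -0.18 (camera adjusted p = 0.266), and with the block 2 fell and 1 rose (5 and 4 adjusted over the list alone). Egln1, an oxygen-sensing hydroxylase, fell with the block (-0.56 ± 0.13, adjusted p = 0.0419), and Adm, which encodes adrenomedullin, had a change of 0.79 ± 0.23 (adjusted p = 0.204).

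**Figure D3:**
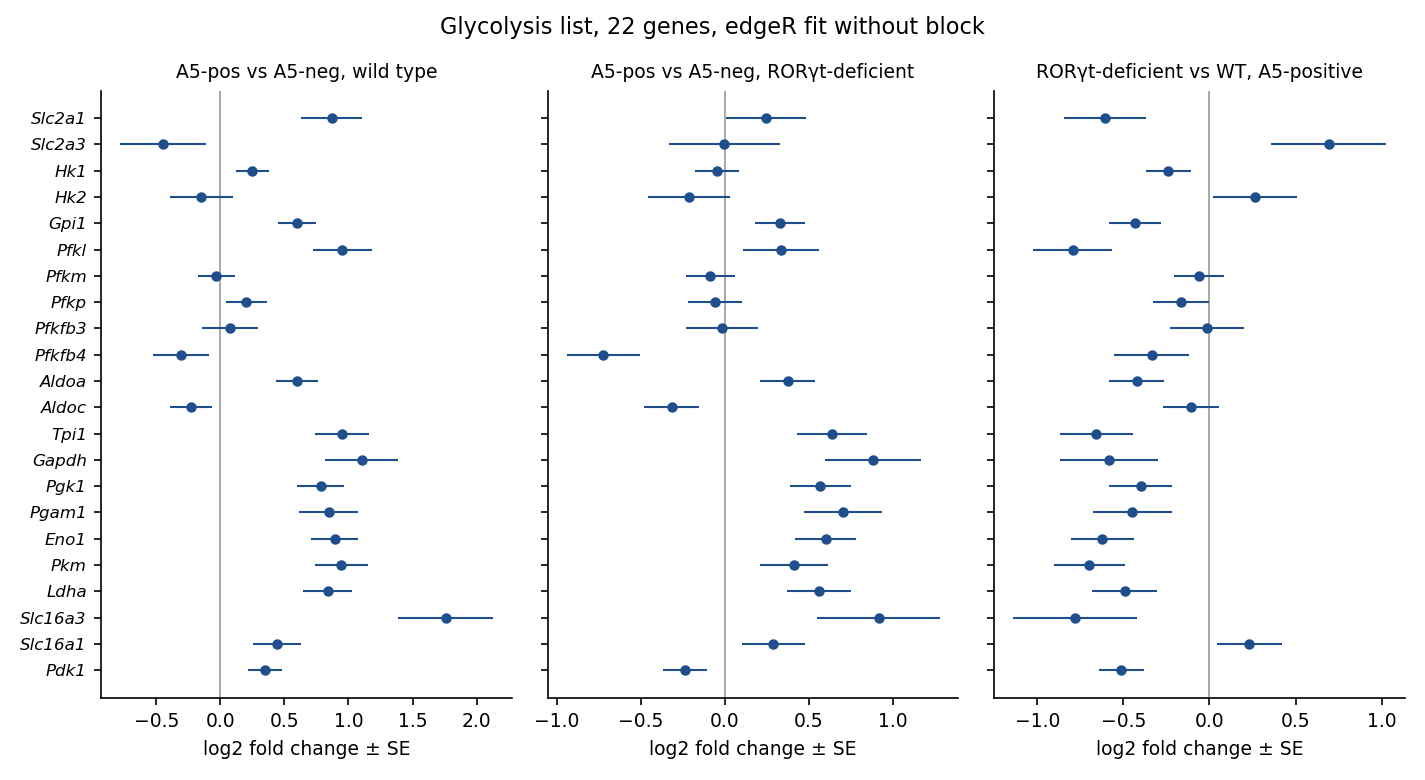
Log2 fold change ± SE of the 22 tested glycolysis genes for the A5 effect in each genotype and for the genotype effect in A5-positive cells. The medians were 0.60 in wild-type and 0.31 in RORγt-deficient mice, and -0.43 for the genotype effect, where Pkm had -0.70 ± 0.21.

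Cholesterol synthesis genes had a median of -0.30 (25 genes, camera adjusted p = 0.00135, and adjusted p = 0.742 with an estimated correlation). With the block 3 fell (12 down and 2 up adjusted over the list alone), among them Mvk, the mevalonate kinase gene (-0.69 ± 0.13, adjusted p = 0.0334), and Lss, the lanosterol synthase gene (-0.70 ± 0.16, adjusted p = 0.0418). All 40 genes of oxidative phosphorylation were below 0, with a median of -0.21 (camera adjusted p = 0.00109, and adjusted p = 0.755 with an estimated correlation). The call ended without wild-type library 1 (-0.02, adjusted p = 0.314) and without RORγt-deficient library 2 (0.02, 0.586), and the median was -0.38 without wild-type library 2 and -0.42 without RORγt-deficient library 1. Uqcrc1, a subunit of respiratory complex III, had a change of -0.46 ± 0.16 (adjusted p = 0.235). Proliferation genes had a median of -0.29 (camera adjusted p = 0.000369, and adjusted p = 0.742 with an estimated correlation), or -0.14 without wild-type library 1 (0.037), and the call ended without RORγt-deficient library 2 (-0.10, adjusted p = 0.362). The mitochondrially encoded genes had a median of 0.30 and passed with the block (camera adjusted p = 0.0431, against 0.389 without it, and adjusted p = 0.633 with the block and an estimated correlation).

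The 33 genes of the IL-17 response of keratinocytes had a median of 0.42 (camera adjusted p = 0.14), with 1 up and 1 down adjusted over the list alone, and 3 up and 1 down with the block over all genes. S100a8, an antimicrobial alarmin, fell with the block (-2.63 ± 0.63, adjusted p = 0.0451) and was low, at 3.24 ± 0.442 and 0.528 ± 0.243 CPM. The cytokine gene Il6 (1.01 ± 0.19, adjusted p = 0.0334) and Nfkbiz, a transcriptional regulator downstream of IL-17 (0.59 ± 0.14, adjusted p = 0.0445), rose with the block. The 19 genes of IL-17 receptor and signalling had a median of 0.30 (camera adjusted p = 0.366), with 2 down adjusted over the list alone, and 3 up and 2 down with the block over all genes. Il17ra, which several IL-17 cytokines share as receptor subunit, rose with the block (0.69 ± 0.14, adjusted p = 0.0378). Il17rc, its partner (-0.62 ± 0.11, adjusted p = 0.0327), and Il22ra1, a subunit of the IL-22 receptor (-1.41 ± 0.26, adjusted p = 0.0334), fell with the block.

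Wound-front genes passed as a list with the block (36 genes, median 0.34, camera adjusted p = 0.00722, against 0.058 without it, and adjusted p = 0.633 with the block and an estimated correlation). With the block 6 rose and 1 fell (12 and 4 adjusted over the list alone). Fosl1, a transcription factor of migrating keratinocytes (0.79 ± 0.17, adjusted p = 0.0378), and Ptgs2, which encodes COX-2 (0.84 ± 0.16, adjusted p = 0.0362), rose with the block, and Stfa1, a stefin, fell (-1.70 ± 0.39, adjusted p = 0.0418). Actin and adhesion genes passed with the block as well (median 0.13, camera adjusted p = 0.0285, against 0.0886, and adjusted p = 0.633 with an estimated correlation), with 2 up (4 adjusted over the list alone). Differentiating keratinocyte genes did so downwards (median -0.21, camera adjusted p = 0.0334, against 0.0859, and adjusted p = 0.633 with an estimated correlation), with 2 down (4 adjusted over the list alone). Tgm3, a transglutaminase of the cornified layer, fell with the block (-2.09 ± 0.37, adjusted p = 0.0327), and so did Krt14 (-0.59 ± 0.13, adjusted p = 0.0395).

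Fibroblast markers had a median of 1.18 with 16 of 17 above 0 (camera adjusted p = 6.02e-05, and adjusted p = 0.742 with an estimated correlation), and 1 rose with the block (5 adjusted over the list alone). Pdgfra rose with the block (1.08 ± 0.25, adjusted p = 0.0442), or by 0.71 without wild-type library 1, and Lum had 165 ± 40.4 and 400 ± 119 CPM (1.28 ± 0.45, adjusted p = 0.238). Matrix genes had a median of 0.37 (camera adjusted p = 0.00922, and adjusted p = 0.742 with an estimated correlation), and this call ended without wild-type library 3 (0.22, adjusted p = 0.179) or RORγt-deficient library 3 (0.24, 0.0863). With the block 2 matrix genes rose (2 adjusted over the list alone). The hair follicle list had a median of 0.22 (24 genes, camera adjusted p = 0.0471, and adjusted p = 0.742 with an estimated correlation), which ended without wild-type library 1 (0.182) or 2 (0.113) and without RORγt-deficient library 1 (0.232) or 3 (0.401), and 2 rose with the block (3 adjusted over the list alone). Dissociation-stress genes had a median of 0.32 with 25 of 26 above 0 (camera adjusted p = 6.02e-05, and adjusted p = 0.742 with an estimated correlation), or 0.21 without wild-type library 1. With the block 2 of them rose (5 adjusted over the list alone), among them Ier3, an early gene of stress (0.52 ± 0.12, adjusted p = 0.0404). Of the stress-response regulators, Atf4 rose with the block (0.54 ± 0.11, adjusted p = 0.0371).

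Among genes of at least log2 CPM 3 whose groups did not overlap, the largest rises with the block were in Gpx3, a secreted glutathione peroxidase (3.01 ± 0.68, adjusted p = 0.0404), Vcam1, an adhesion molecule (2.02 ± 0.36, adjusted p = 0.0327), Krt24 (1.82 ± 0.34, adjusted p = 0.0331), Tnfaip6, a hyaluronan-binding protein of inflamed tissue (1.81 ± 0.27, adjusted p = 0.0175), Serpina3n (1.77 ± 0.32, adjusted p = 0.0331) and the complement gene C3 (1.77 ± 0.42, adjusted p = 0.0436). Tnfaip6 and Serpina3n had 7.21 ± 3.73 and 2.31 ± 0.976 CPM in the RORγt-deficient A5-negative cells against 299 ± 79.4 and 184 ± 55.8 CPM in the A5-positive cells, the libraries with the high fibroblast markers. Among the largest falls, beside Thbd, were the membrane protease gene Tmprss11g (-1.97 ± 0.44, adjusted p = 0.0404), Fgfbp3, which encodes a growth factor binding protein (-1.62 ± 0.26, adjusted p = 0.024), and the scavenger receptor gene Stab1 (-1.53 ± 0.29, adjusted p = 0.036). Among the 6 libraries left out singly, only wild-type library 1 ended the call of Thbd with the block (adjusted p = 0.0527). Thbd also lost this call without all libraries numbered 2 and with the fibroblast covariate, since 0 genes fell in either fit.

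**Figure D4:**
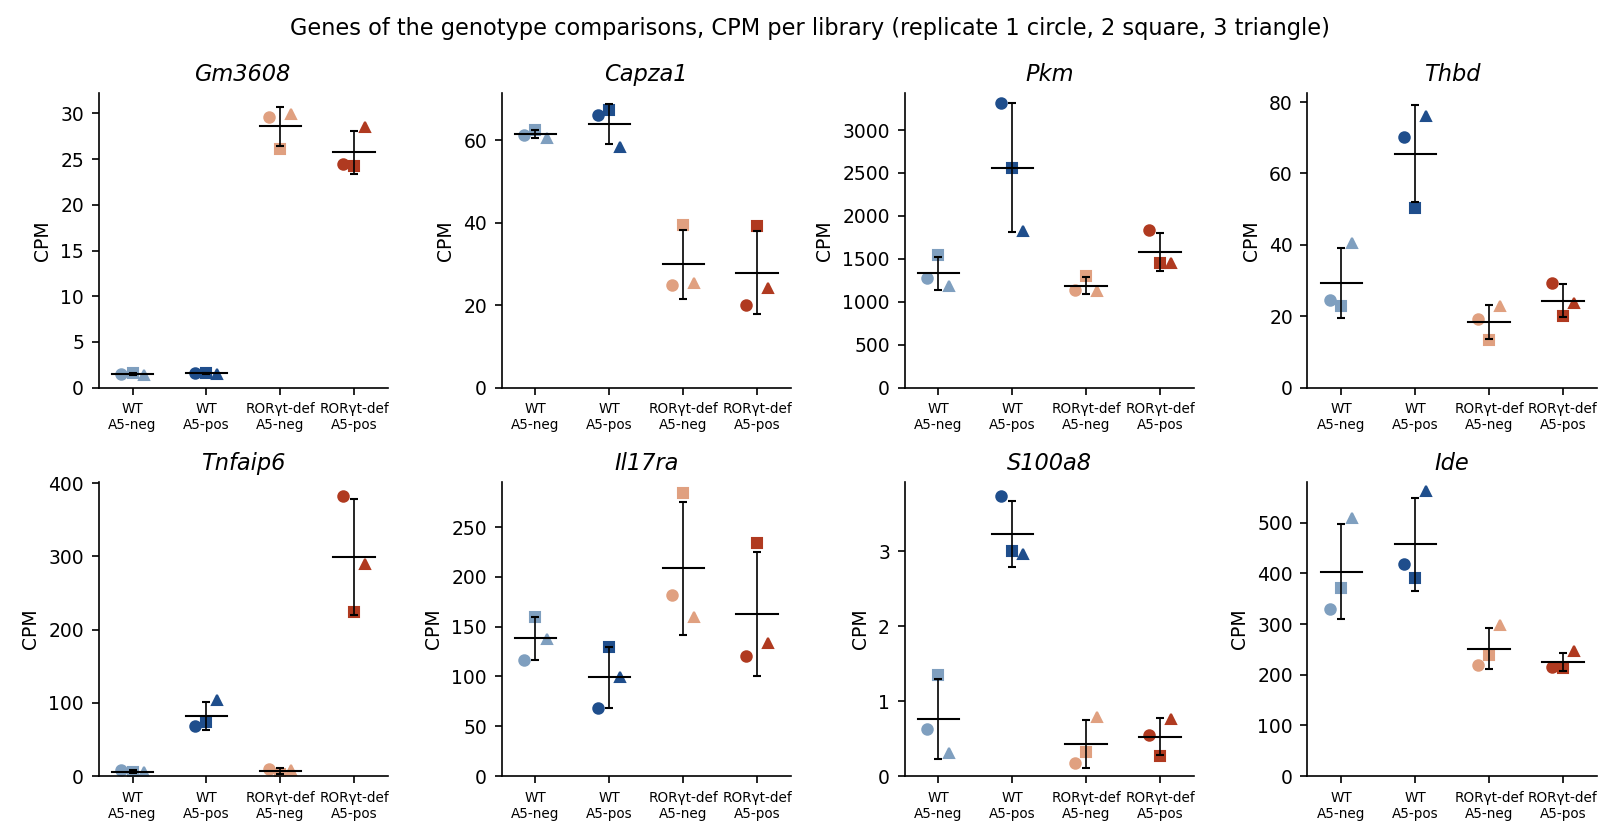
Levels of 8 genes in each of the 12 libraries, in TMM-scaled CPM, with points for libraries and the mean ± SD of each group (n = 3). Gm3608 was at 1.47 ± 0.0786 and 1.57 ± 0.0664 CPM in the wild-type groups and at 28.6 ± 2.14 and 25.7 ± 2.39 CPM in the RORγt-deficient groups.

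The genotype effect in A5-negative cells asked the same of the wound edge. Proliferation and oxidative phosphorylation genes were lower as lists in RORγt-deficient cells, and wound-front and dissociation-stress genes were higher. The call for wound-front genes ended without a single library, as given below. Top2a was at 82.8 ± 2.93 CPM in wild-type and 57.8 ± 15.4 CPM in RORγt-deficient cells (-0.52 ± 0.21, adjusted p = 0.779), and Ptgs2 at 201 ± 47.4 and 402 ± 96.9 CPM (1.0 ± 0.27, adjusted p = 0.779). Gm3608 rose by 4.28 ± 0.16 (adjusted p = 5.63e-08).

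Gm3608 was the single gene of 16677 that passed by edgeR, with and without the block. DESeq2 called 19 and voom 7, and 849 genes had an unadjusted p under 0.05 (2522 with the block), where 834 are expected. With the block the count was 2 without wild-type A5-negative library 1 and 4 without RORγt-deficient A5-negative library 3, and DESeq2 with the block called 634. Groups did not overlap for 2601 genes (15.6%), against 10% by chance.

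Proliferation genes had a median of -0.44 with 2 of 40 above 0 (camera adjusted p = 8.06e-11, and adjusted p = 0.745 with an estimated correlation), and 14 fell with the block adjusted over the list alone. Birc5, which encodes survivin, had a change of -0.92 ± 0.41, and the checkpoint kinase gene Bub1b one of -0.67 ± 0.24 (adjusted p = 0.779 for each). All 40 genes of oxidative phosphorylation were below 0, with a median of -0.34 (camera adjusted p = 6.05e-09, and adjusted p = 0.745 with an estimated correlation). Ndufb9, a subunit of respiratory complex I, had a change of -0.51 ± 0.25, and Sdhd one of -0.57 ± 0.29 (adjusted p = 0.779 for each). Cholesterol synthesis genes had a median of -0.20 (camera adjusted p = 0.00141, and adjusted p = 0.745 with an estimated correlation). That call ended without wild-type A5-negative library 3 (adjusted p = 0.127) or RORγt-deficient A5-negative library 1 (0.273), and the median was -0.33 and -0.32 without wild-type library 1 or 2 and -0.41 without RORγt-deficient library 3.

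Wound-front genes had a median of 0.27 with 29 of 36 above 0 (camera adjusted p = 0.00146, and adjusted p = 0.745 with an estimated correlation), which ended without wild-type A5-negative library 1 (0.22, adjusted p = 0.0568). With the block 11 rose and 1 fell adjusted over the list alone. The stromelysin gene Mmp3 had 30 ± 20.6 and 124 ± 98.0 CPM (2.05 ± 0.59, adjusted p = 0.779), with a change of 1.22 to 2.68 over the left-out libraries. Dissociation-stress genes had a median of 0.30 with 25 of 26 above 0 (camera adjusted p = 3.29e-06, and adjusted p = 0.745 with an estimated correlation), or 0.18 without RORγt-deficient library 2, and 1 rose with the block adjusted over the list alone. Matrix genes had a median of 0.33 (camera adjusted p = 0.0194, and adjusted p = 0.745 with an estimated correlation). That call ended without wild-type library 1 (0.25, adjusted p = 0.121) or 3 (0.14, 0.127) and without RORγt-deficient library 1 (0.05, 0.731), and 3 rose and 1 fell with the block adjusted over the list alone. Fibroblast markers had a median of 0.13, while the list test pointed down (camera adjusted p = 0.525).

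The IL-17 receptor and signalling genes passed with the block (19 genes, median 0.15, camera adjusted p = 0.0194, against 0.0966 without it, and adjusted p = 0.317 with the block and an estimated correlation), with 6 up adjusted over the list alone. Il17ra was at 138 ± 21.7 and 208 ± 66.8 CPM (0.59 ± 0.30, adjusted p = 0.779), with a change of 0.297 to 0.741 over the left-out libraries. The IL-17 response genes had a median of 0.25 (camera adjusted p = 0.411). Il6 had a change of 0.56 ± 0.23 and Lcn2, an iron-binding antimicrobial protein, one of -0.74 ± 0.30 (adjusted p = 0.779 for each). Sebocyte markers passed with the block (median -0.68, camera adjusted p = 0.0387, against 0.132 without it, and adjusted p = 0.741 with the block and an estimated correlation). Slc2a1 had a change of 0.02 ± 0.24 (adjusted p = 0.989) and Hif1a of 0.13 ± 0.15 (adjusted p = 0.833), and glycolysis genes had a median of -0.01 (camera adjusted p = 0.512).

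After Gm3608, genes of at least log2 CPM 3 with small p-values were Gcc1, a Golgi protein (0.52 ± 0.12), Ust, a sulfotransferase of glycosaminoglycans (0.55 ± 0.13), and Ptger4, a prostaglandin receptor (0.68 ± 0.17), above 0. Below 0 were Capza1, an actin capping subunit (-1.04 ± 0.24), and Mab21l3 (-1.01 ± 0.23). Their adjusted p-values were 0.738 to 0.779.

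The sequence closest to Gm3608 was Capza1 on chromosome 3 (104822779 to 104864505), with 99.5% identity over 2859 bases. Capza1 fell with the block in A5-positive cells (-1.25 ± 0.17, adjusted p = 0.0157), which ended without wild-type A5-positive library 1 (0.0746) or RORγt-deficient A5-positive library 3 (0.0599), and had an adjusted p of 0.0841 with the block in A5-negative cells. The sum of Capza1 and Gm3608 was 62.9 ± 1.05 and 58.5 ± 6.18 CPM in wild-type and RORγt-deficient A5-negative cells and 65.4 ± 4.94 and 53.6 ± 9.45 CPM in A5-positive cells. Whether reads of Capza1 were counted at Gm3608 cannot be told, since the treatment of reads that match several places is not given. The rise of Gm3608 is therefore not shown to be a change in transcription.

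The interaction asked whether the A5 effect differs between the genotypes. By the list test at the preset correlation, fibroblast markers had a larger A5 effect in RORγt-deficient mice and glycolysis genes a smaller A5 effect. Neither list passed with an estimated correlation. Lum had an interaction of 2.15 ± 0.66 and Dcn of 2.32 ± 0.69, and the glycolytic genes Pkm, Pfkl and Pdk1 had -0.53 ± 0.29, -0.62 ± 0.32 and -0.58 ± 0.18 (adjusted p = 1 for each). With each library left out in turn, Lum ran from 1.31 to 2.58 and Dcn from 1.38 to 2.67. Pkm ran from -0.667 to -0.272, Pfkl from -0.770 to -0.396 and Pdk1 from -0.639 to -0.458. Slc2a1 had -0.63 ± 0.34 and Hif1a -0.35 ± 0.22 (adjusted p = 1 for each). Over the left-out libraries they ran from -0.749 to -0.202 and from -0.442 to -0.201.

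By edgeR 0 of 16677 genes passed, with and without the block, and 458 had an unadjusted p under 0.05 (910 with the block), where 834 are expected. DESeq2 called 4 and voom 0, and DESeq2 with the block 93. The smallest p-values were those of Ltbp1, a regulator of TGF-beta (0.80 ± 0.18), Igsf10 (1.5 ± 0.35) and Serpina3n (1.94 ± 0.52) above 0, and of Cnnm3 (-0.62 ± 0.18) and the leukotriene receptor gene Ltb4r2 (-0.81 ± 0.24) below 0.

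The fibroblast list had a median interaction of 1.01 with 15 of 17 above 0 (camera adjusted p = 1.02e-07, and adjusted p = 0.687 with an estimated correlation). The median was 0.67 without wild-type A5-negative library 3, 2.36, 0.59 and 0.64 without RORγt-deficient A5-negative library 1, 2 or 3, and 0.58 without RORγt-deficient A5-positive library 3. The glycolysis list had a median of -0.27 with 1 of 22 above 0 (camera adjusted p = 0.000892, and adjusted p = 0.687 with an estimated correlation). It ended without wild-type A5-positive library 1 (-0.06, adjusted p = 0.137) and had -0.17 without RORγt-deficient A5-positive library 2. The hair follicle list had a median of 0.16 (camera adjusted p = 0.0103, and adjusted p = 0.687 with an estimated correlation). Cd34 (2.22 ± 0.64) and Fst, which encodes follistatin (0.66 ± 0.25), were its members with the smallest p (adjusted p = 1 for each). Its call ended without wild-type A5-negative library 2 (0.131) or 3 (0.163), wild-type A5-positive library 1 (0.136), RORγt-deficient A5-negative library 3 (0.0877) and RORγt-deficient A5-positive library 1 (0.0709) or 3 (0.218).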

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

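The test without wild-type A5-positive library 1, the intervals over list members and the demand that fits with and without the block give the same answer were chosen only after the result was seen, and the fibroblast covariate after the data were seen but before its result.

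Of the gene lists, 3 passed the test of the interaction itself by camera at the preset correlation of 0.01. Fibroblast markers had an adjusted p of 1.02e-07 with a median difference of 1.01, glycolysis genes an adjusted p of 0.000892 with a median of -0.27, and hair follicle genes an adjusted p of 0.0103 with a median of 0.16. Each had an adjusted p of 0.687 with an estimated correlation, and by edgeR 0 genes passed the interaction. The fibroblast markers had a median pairwise correlation of 0.789 between the A5-positive libraries, far above the preset value. Their p at the preset value therefore overstates the support. The glycolysis call ended without wild-type A5-positive library 1, and the hair follicle call without any of several libraries, as given above. A difference between the genotypes is not established for these lists.

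RNA of fibroblasts in the A5-positive sort is a candidate explanation for the fibroblast genes, although the gate asked for Epcam and integrin alpha6. The 17 markers varied in step between the A5-positive libraries, with a median pairwise correlation of 0.789 after group means, against a median of -0.02 and a 95th percentile of 0.310 in 1000 random lists matched on level and spread, and Col3a1 reached 5634 ± 1258 CPM in RORγt-deficient A5-positive cells. Mesenchymal genes expressed by the keratinocytes themselves cannot be told apart from it: of 6 epithelial genes, 2 (Cdh1 and Cldn1) fell with the block in both genotypes, calls that leaving out a library could end, as it could for Epcam, which fell in wild-type mice only, and for the rise of Krt14 in RORγt-deficient mice (0.0559 to 0.121 without 4 of the 6 libraries), while Dsp fell in RORγt-deficient mice only, and Krt5 and Krt14 rose in wild-type mice. A larger share of fibroblast RNA was examined as the whole source of the rises called with the block for the genotype in A5-positive cells. Of these, 254 of 377 (67.4%, 95% Clopper-Pearson interval 62.4% to 72.1%, which takes genes as independent) had an A5 effect below 0 in RORγt-deficient mice, where the markers were high in the A5-positive fraction. By the bound set beforehand this argued against that explanation. The median A5 effect of all genes there was -0.000335, so genes taken at random would pass that bound as well, and the test cannot decide. That explanation stays open for all these rises. With the marker mean as a covariate and the block 1 of the 670 calls was left. This does not decide it either, since the covariate nearly follows A5 status and left 0 genes in both A5 effects as well. Whether the share of such RNA follows the genotype or the dissection and sorting of each pool was not tested.

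The glycolysis genes were lower in RORγt-deficient A5-positive cells by a median of -0.43, and a single library is a candidate explanation: without wild-type A5-positive library 1 the median was -0.22, or 52.1% of its size (33.7% to 83.2% over list members), with 18 of 22 genes below 0. With the block 63.0% was kept (48.5% to 89.2%), and these intervals, which cover the list members and not the libraries, leave that explanation open. A larger share of fibroblast RNA was tested with the marker mean as a covariate, where the median of -0.32 kept 75.3% (61.5% to 130%). By the bound set beforehand this would exclude the explanation, but with the covariate and the block the median was -0.15, or 36.4% (12.2% to 79.1%), so the fits disagree and it stays open under the demand added later. An effect of the lack of RORγt itself stays open beside both and cannot be told apart from them with these 6 libraries.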

How the results depend on the processing

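The fits without all libraries of a number, with the fibroblast covariate, and with the block joined to another choice were chosen after seeing the data. Where a count or a direction moved, the cause was not tested, except for the covariate, which by its construction nearly follows A5 status. The counts for the genotype effect in A5-positive cells, the genotype effect in A5-negative cells, the A5 effect in wild-type mice, the A5 effect in RORγt-deficient mice and the interaction were 1, 1, 575, 921 and 0. They were 380, 19, 1327, 1598 and 4 by DESeq2. Without a filter the first 3 were 67, 7 and 939, and by voom the first 4 were 5, 7, 989 and 1566. The block gave 670, 2394 and 2937 for the A5-positive genotype effect and the A5 effects, and the block by genotype and number 2407 and 2893 for the A5 effects. In the 6 compared libraries alone the A5 effect in wild-type mice had 344. With the covariate both A5 effects had 0, with and without the block. RLE factors and the stricter filter moved no count by more than 1.5 times. With the block, the 5 counts of 670, 1, 2394, 2937 and 0 became 2073, 634, 3533, 4030 and 93 by DESeq2. By voom with the block the genotype effect in A5-negative cells had 2 and the A5 effect in RORγt-deficient mice 1908. The genotype effects in A5-positive and A5-negative cells had 7 and 5 in the 6 compared libraries with the block, and 1 and 4 with the covariate and the block.

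Leaving out a library, or all 4 of a number, gave 1 to 2 genes for the genotype effect in A5-positive cells, 38 to 569 for the A5 effect in wild-type mice and 135 to 1731 in RORγt-deficient mice. With the block the ranges were 1 to 705 and 1 to 4 for the genotype effects in A5-positive and A5-negative cells, and 272 to 2357 and 730 to 2960 for the A5 effects. The interaction had 0 genes in all of these by edgeR.

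Pecam1 in the A5 effect of wild-type mice, 1.02 at first, turned to -0.15 by voom and -0.044 with the block by genotype and number, and ran from -1.94 without A5-positive library 1 to 1.87 without A5-negative library 1. It was -1.07 without all libraries numbered 1. With the covariate, Epcam (0.13), Col3a1 (-1.41), Il17ra (0.70) and Cdh1 (0.44) turned in wild-type mice, and Col3a1 (-1.65), Saa3 (-5.08) and Cdh1 (0.67) in RORγt-deficient mice. Of the list tests that turned, macrophage markers in the genotype effect in A5-negative cells had an adjusted p of 0.0101 (down) without wild-type A5-negative library 2, in a range of 4.93e-06 to 0.960 over the left-out libraries. Langerhans and dendritic cell markers there had 0.0419 (up) without library 1, in a range of 0.0198 to 0.656. Macrophage markers in the interaction had 0.00952 (down) without that library, in a range of 0.00299 to 0.988.

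Of 145 list tests, 107 kept their side of the threshold with an estimated correlation and 38 lost the call, and with fry 116 kept their side, 27 lost the call and 2 gained it. The block changed the 12 list calls given above and no other, and a prior count of 0.5 changed none. RLE factors changed 1 list call and 1 named gene. The named genes kept direction and side in 117 of 151 cases by DESeq2 and in 97 of 151 with the block, and all the others gained a call. Depth set a limit as well, since a count of 0 allows up to 3 counts, or 0.0403 to 0.103 CPM of the total counts by library.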

Other observations

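The count of genes with the same genotype difference in both fractions and the test of immune markers among the 125 genes were chosen only after the result was seen, and the genes Gm3608, Gm7665, 4930481B07Rik, Klk13, Ide, Mmp10, Igfbp3, Cdh1, Cldn1, Dsp and Cd3e were named after their values were seen.

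Some genes outside the rule moved with the genotype in A5-positive cells. Ide, which encodes the insulin-degrading enzyme (chromosome 19, 37268743 to 37337852), fell with the block (-1.0 ± 0.10, adjusted p = 0.00652), from 458 ± 92.2 to 226 ± 17.9 CPM. Klk13, a kallikrein-related protease gene (chromosome 7, 43712567 to 43727534), fell with the block as well (-2.63 ± 0.28, adjusted p = 0.00652), from 20.2 ± 8.28 to 3.29 ± 1.69 CPM. Both kept the call with the block without each of the 6 compared libraries, and Klk13 passed without the block when RORγt-deficient A5-positive library 1 was left out (adjusted p = 0.0294). Both lost the call with the block without all libraries numbered 2 and with the fibroblast covariate, since 0 genes fell in either fit. The protease gene Mmp10 (2.19 ± 0.27, adjusted p = 0.0123) and Igfbp3, a binding protein of insulin-like growth factors (1.17 ± 0.20, adjusted p = 0.0308), rose with the block, but their groups overlapped and the limits given for the other genes named with the block hold for them. In the A5 effect Cdh1, the E-cadherin gene, fell with the block by 0.50 ± 0.13 in wild-type (adjusted p = 0.032) and 0.56 ± 0.13 in RORγt-deficient mice (adjusted p = 0.018), and Cldn1, a claudin of tight junctions, by 0.82 ± 0.18 (adjusted p = 0.016) and 0.60 ± 0.18 (adjusted p = 0.042). In wild-type mice these calls ended without A5-negative library 1 (adjusted p = 0.0659 for Cdh1 and 0.0603 for Cldn1) or 3 (0.145 and 0.0871) and A5-positive library 1 (0.121 and 0.0812) or 2 (0.126 and 0.0788), and for Cdh1 without A5-negative library 2 (0.0707). In RORγt-deficient mice they ended without A5-negative library 1 (0.0605 and 0.183) and A5-positive library 1 (0.0868 and 0.128) or 3 (0.0864 and 0.178), and for Cldn1 without A5-negative library 2 (0.0892). Dsp, the desmoplakin gene, did not pass in wild-type mice (-0.28 ± 0.17, adjusted p = 0.355, and 0.219 with the block). It fell without the block in RORγt-deficient mice (-0.73 ± 0.17, adjusted p = 0.0259), which ended without A5-negative library 1 (0.0669) or 3 (0.0986) or A5-positive library 1 (0.117) or 3 (0.103). With the block it fell there as well (-0.74 ± 0.14, adjusted p = 0.00658), and no left-out library ended this (highest 0.0454).

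Of the lists not yet described, T cell markers had a median of 0.01 in the A5 effect of wild-type mice (6 genes, camera adjusted p = 0.881), neutrophil markers -0.22 (7 genes, 0.485), endothelial markers 1.53 (11 genes, 0.485), melanocyte markers -0.19 (4 genes, 0.51, with a mean of 0.21), muscle markers 0.22 (5 genes, 0.485), adipocyte markers -0.63 (3 genes, 0.278) and erythroid markers -0.39 (3 genes, 0.625). The endothelial markers summed to 100.8 CPM of the total counts in wild-type A5-positive library 1 and to 16.0 to 40.7 CPM in the others. The mTORC1, AKT and ERK pathway had a median of -0.01 (30 genes, camera adjusted p = 0.67). Schwann cell markers had 2 tested genes and mast cell markers 0, so neither was tested. The IL-17 response genes had a median of 0.04 and a mean of 0.18, while their list test pointed down (camera adjusted p = 0.696). In the genotype effect in A5-negative cells macrophage markers had a median of -0.44, while their test pointed up (camera adjusted p = 0.976). Median, mean and test also differed in sign for the stress-response list in both genotype effects, for muscle, erythroid, adipocyte and Langerhans markers in the genotype effect in A5-positive cells, and for hair follicle genes in the A5 effect of wild-type mice. The same held for the mTORC1 list and endothelial markers in the A5 effect of RORγt-deficient mice and for matrix and IL-17 receptor genes in the interaction.

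The same genotype difference in both fractions was seen with the block in 388 genes (p under 0.01 with the same sign). If the fractions were independent 42.5 would be expected, but they were not. Both comparisons came from 1 fit with the same spread per gene and the same block. Residuals after group means also correlated between the fractions for libraries of the same genotype and number (0.208 to 0.690). The number of 388 against 42.5 is therefore no support for an effect of the genotype. Whether the fractions share their pools of mice is not given in the sources used here. Among the 388 genes were Gm3608, given above with Capza1, and Gm7665 (chromosome 18, 16274648 to 16274944; 2.66 ± 0.36 and 2.38 ± 0.36 in A5-positive and A5-negative cells), whose closest sequence was S100a11 at 98.7% identity over 297 bases. Another was 4930481B07Rik (chromosome 3, 95015625 to 95020138; 2.50 ± 0.37 and 2.43 ± 0.37).

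Splits of the 6 libraries of a comparison into groups of 3 number 10, too few for a share under 0.05. For the genotype effect in A5-positive cells 1 split, the real one, gave as many genes (1, highest other 0, and 670 and 0 with the block), and so it was for the A5 effects in wild-type mice (575 and 0, and 2394 and 0 with the block) and RORγt-deficient mice (921 and 0, and 2937 and 0 with the block). For the genotype effect in A5-negative cells 2 splits did (real 1, highest other 125, and 1 and 2 with the block). Of the 10 splits 4 part all 3 pairs of numbers, and the other 3 of these gave 0 genes each in every comparison. The split with 125 genes put wild-type A5-negative library 1 with RORγt-deficient A5-negative libraries 1 and 3, and all 125 were higher in these, which points to a structure of the samples. Of 44 immune markers tested 5 were among the 125 (odds ratio 17.6, Fisher's exact test, p = 1.88e-05, which takes genes as independent). Ptprc, itself among the 125 and so no separate support, was at 42.4, 25 and 22.3 CPM of the total counts in these libraries and at 2.75, 10.7 and 3.31 CPM in the other 3.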
